A study of Capsicum annuum and Capsicum chinense and Capsicum annuum var. glabriusculum with 33 samples.

How the data were processed

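RNA of 33 pepper samples was measured by strand-specific sequencing of poly(A) RNA with paired reads on a HiSeq 2000, per the labels' protocols. The deposited table gives RPKM per gene and library, normalised by the authors per kilobase of gene model and by the read total of the library. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. No replicate was pooled, each column belongs to 1 library, and 0 further columns were left unused.

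Because a gene's RPKM in a library is a whole multiple of the value of 1 read, the steps between values gave each gene's length and each library's read total. Lengths were sought only among multiples of 3, as for coding sequence. This worked for 25556 of the 31426 genes, those above 0 in at least 10 libraries with a step that could be read, and 99.98% of their values came out whole within a tolerance of 0.01 reads. A length was kept only where it made the lowest values of a gene whole. That share is therefore partly fixed by the choice of genes and is no independent check. The recovered lengths had a median of 969 bases. The multiple of 3 was a setting on which the read totals rest, so whether the gene models hold coding sequence only was not tested. The 25556 genes with a recovered length held 94.1% to 98.1% of each recovered total, and the RPKM of a library over all genes summed to between 935999 and 1.12e+06. The closest pair of libraries differed by a chi-square of 58.5 per gene, far above sampling noise, so no library was counted as a duplicate. The recovery was tested on simulated counts before use, with simulated lengths that were also multiples of 3. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

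The IDs were used as the file gives them. None of the 31426 matched the table of gene names for the assembly UCD10Xv1.1 (0 matches), and 376 were at 0 in every library. The gene lists that were fixed by product names before the data were examined are therefore void, and named genes are the 2 largest rises and the 2 largest falls of a comparison among genes past the threshold that had a mean of at least 10 RPKM in the higher arm and no overlap of the arms (for blocked comparisons, all pairs in 1 direction). For the organ contrasts the text gives the largest rise per organ, and for fruit also the largest fall. Genes on in some lines and off in others were named by the highest RPKM. The second highest of these was Capana01g003500, described in the ripening comparisons, so the third is given beside the first.

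Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(RPKM + 1), two-sided, for genes at 1 RPKM or more in at least as many libraries as the smaller arm, and in at least 2 libraries for the organ contrasts. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(RPKM + 1) scale. The tests treat stages, lines or organs as replicates, because each was 1 library. Zunla 1 fruit at 3, 5 and 7 days after breaker was compared with 5 earlier stages, fruit 5 days after breaker of 3 C. annuum lines with mature green fruit of 9 lines, HYL with Zunla 1 over 5 organ pairs with the pair as a block, with an interaction of fruit against vegetative organs, chiltepin with Zunla 1 (3 against 4 libraries) with organ as a block, and each of 5 organs with the mean of the others in 1 fit of 16 libraries with line as a covariate. These designs, the named gene rule and most alternatives were fixed before the data were examined.

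The lines ZL1, ZJ49 and HYL had both mature green fruit and fruit 5 days after breaker, and the line names of the labels pair them. Deviations from the stage means correlated across genes within a line at r of 0.36, 0.38 and 0.59, above the highest value with another line of 0.14, 0.04 and -0.40.

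Organ gene groups were taken after the data were seen, because names were lacking, from the libraries without fruit (adjusted p under 0.05 and at least 2 log2 units above each other organ) and tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 4 groups. The ripening position is the mean log2(RPKM + 1) of the Zunla 1 rises minus that of the falls, among called genes with at least a 2-fold change, set to 0% and 100% at the means of the Zunla 1 stages before and after breaker. Alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, leaving out each library, other blocks and other sets of libraries. On simulated data with 200 changed genes, the fits recovered 60.0% of 4-fold and 87.5% of 16-fold changes for Zunla 1 ripening (19368 genes), 66.7% and 95.0% for the lines (20318 genes), 61.7% and 96.3% for HYL (18332 genes) and 18.3% and 87.5% for chiltepin (19451 genes). In the 5 organ contrasts they recovered between 16.7% (stem, 23244 genes) and 61.7% (fruit, 23270 genes) of 4-fold changes. At 2-fold they recovered 5.00%, 13.3%, 3.33% and 0% in the first 4 of these, so small changes were mostly out of reach. For the interaction of HYL the values were 0% at 2-fold, 8.33% at 4-fold and 78.8% at 16-fold (18570 genes), with 16 false calls. Figures were drawn with matplotlib 3.10.9.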

Results

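Poly(A) RNA of pepper (Capsicum) organs was sequenced in 33 libraries, and the expression of 31426 predicted genes was given as RPKM, the reads of a gene per kilobase of its model, scaled by the read total of the library. The line Zunla 1 (C. annuum) had root, stem, leaf, bud and open flower and 9 fruit stages, from fruit of 0 to 1 cm over mature green to 7 days after breaker, the stage at which green fruit starts to change colour. Mature green fruit came from 9 C. annuum lines and fruit 5 days after breaker from 3 C. annuum lines, ZL1 (Zunla 1), ZJ49 and ZJ7, of which ZJ7 had no mature green library. HYL (C. chinense) had root, stem, leaf, mature green fruit and fruit 5 days after breaker, and chiltepin, a wild pepper, had leaf, a flower mix and breaker fruit. A breaker fruit library whose labels name both HYL and Zunla 1 entered no comparison. Each line, organ and stage was 1 library, so the p-values below measure the spread between stages, lines or organs, not between plants.

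The steps between the values gave the read total of each library, with gene lengths taken as multiples of 3. The libraries fell into a shallower set of 25 libraries with totals of 12691809 to 15864306 reads and a deeper set of 8 libraries with 25923891 to 31213971 reads. The deeper set held the 3 chiltepin libraries and mature green fruit of the lines 11c255, 11c320, G16, T803 and SP3. The last is titled SP3 and described under another line name, and without it the counts given below were 3796 genes for ripening across lines and 818 for genes on in 1 line and off in another. A gene of 1 kb with 3 reads had an RPKM of 0.189 to 0.236 in the shallower and of 0.0961 to 0.116 in the deeper libraries, a floor that covers counting error only. The IDs of the table were not paired with gene names in the files used here, so genes are described through the stages, organs and lines in which they were high.

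The Zunla 1 fruit series addressed which genes change as fruit ripens. Fruit at 3, 5 and 7 days after breaker differed from the 5 earlier stages in 4292 of 19771 genes, of which 1215 rose and 3077 fell, and 3880 of the changes were at least 2-fold. The gene Capana06g000615 was at 1.22 ± 1.61 RPKM (SD, n = 5) before breaker and at 10140 ± 2766 RPKM (SD, n = 3) after it, with 1583 RPKM in breaker fruit. Capana01g003500 went from 26.9 ± 59.9 RPKM (SD, n = 5) to 10679 ± 9749 RPKM (SD, n = 3). In the opposite direction, Capana00g000315 fell from 8500 ± 5467 RPKM (SD, n = 5) to 1.69 ± 1.60 RPKM (SD, n = 3), and Capana10g000283 fell from 9600 ± 11507 RPKM (SD, n = 5) to 0.488 ± 0.388 RPKM (SD, n = 3). Both of these were already low at mature green, at 35.5 and 3.17 RPKM.

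With limma on log2(RPKM + 1) and Benjamini-Hochberg adjustment, Capana06g000615 had a log2 fold change of 12.43 (SE 0.549, adjusted p = 8.28e-05) and Capana00g000315 of -10.42 (SE 1.83, adjusted p = 0.00758). The limma values were 11.34 (SE 1.64, adjusted p = 0.00387) for Capana01g003500 and -10.06 (SE 2.51, adjusted p = 0.0245) for Capana10g000283, and the last lost its call when any of the stages 3, 5 or 7 days after breaker, 1 to 3 cm or 4 to 5 cm was left out, with adjusted p between 0.0521 and 0.0834. These folds are on the log2(RPKM + 1) scale, which understates the change of low genes. Median-of-ratios scaling moved the median log2 change of all genes from -0.31 to -0.05, a shift of 0.26, and then 2168 genes rose and 2671 fell, so the excess of falls shrank from 28.3% rises among the calls to 44.8%. The count was 1288 without the stage 7 days after breaker, 1712 without 5 days after, 2561 without 1 to 3 cm, 2670 without 4 to 5 cm, 1894 without the 2 smallest stages together and 6958 without mature green.

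Along the 9 Zunla 1 stages, the number of genes at 1 RPKM or more was 18967 in fruit of 0 to 1 cm, 18144 at mature green, 17252 at breaker and 16890 at 7 days after breaker. Among 8354 genes that reached 5 RPKM and varied at least 4-fold, 1891 (22.6%) had their highest value in the smallest fruit and 1323 (15.8%) in fruit of 1 to 3 cm, while 229 (2.74%) were highest at breaker and 988 (11.8%) at 3 days after breaker. Between neighbouring stages, 1929 genes differed at least 4-fold from fruit of 4 to 5 cm to mature green fruit (633 higher, 1296 lower), 1670 from 3 to 5 days after breaker and 303 from the smallest fruit to 1 to 3 cm. Scaling turned the order of the first 2 of these steps, with 1624 genes in the first (864 higher, 760 lower) and 1728 in the second (919 higher and 809 lower, from 769 and 901). The 10 most abundant genes held 38.9% of the summed RPKM in mature green and 37.5% in breaker fruit of Zunla 1, against 12.8% in fruit of 4 to 5 cm.

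In breaker fruit, the genes that rose at least 2-fold after breaker had made a median of 29.8% of their change, and those that fell had made 70.2%. At mature green the medians were 0% and 36.0%. With scaling, where 1619 genes rose and 2354 fell at least 2-fold, the breaker values were 43.5% and 57.9% and the mature green values 11.2% and 24.7%, so the order held and the gap narrowed. These stages are single libraries, and the difference between the medians was not tested. Of the 1070 genes that rose at least 2-fold, 63 (5.89%) were under 1 RPKM in all 5 other Zunla 1 organs, and of the 2810 that fell, 43 (1.53%) were.

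Across C. annuum lines, fruit 5 days after breaker (3 lines) differed from mature green fruit (9 lines) in 4475 of 20719 genes, of which 1516 rose and 2959 fell. The same 2 IDs led the rises as in the Zunla 1 series, whose Zunla 1 libraries at these stages are part of both comparisons. Capana01g003500 was at 13970 ± 6525 RPKM (SD, n = 3) against 407 ± 1170 RPKM (SD, n = 9), and Capana06g000615 at 6969 ± 1710 RPKM (SD, n = 3) against 146 ± 433 RPKM (SD, n = 9). Among the falls, Capana08g002529 was at 2.02 ± 0.784 RPKM (SD, n = 3) against 3494 ± 3395 RPKM (SD, n = 9), and Capana00g001863 at 0.545 ± 0.515 RPKM (SD, n = 3) against 1520 ± 1584 RPKM (SD, n = 9).

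The limma log2 fold changes were 11.16 (SE 2.20, adjusted p = 0.00511) for Capana01g003500, 10.51 (SE 1.66, adjusted p = 0.00163) for Capana06g000615, -8.48 (SE 1.87, adjusted p = 0.00878) for Capana08g002529 and -8.34 (SE 1.85, adjusted p = 0.00905) for Capana00g001863. All fruit 5 days after breaker was in the shallower set, and within that set (4 mature green lines) 190 genes passed, 101 higher and 89 lower. Leaving out mature green fruit of ZJ49 there as well raised the count to 746, so the drop from 4475 cannot be put down to the depth set alone. Both settings were chosen after the data were seen. All 4 named genes lost their calls within that set, at limma adjusted p between 0.0695 and 0.133. Of the genes called in the full fit, 4324 were tested there, and 100% kept their sign. Their median absolute log2 fold change was 1.48, against 1.78 in the full fit, so most of the change remained. These genes were chosen with the same libraries, so their signs are no independent test. With the depth set as a term in the model 2174 genes passed, 786 higher and 1388 lower. All 4475 genes kept their sign in that fit, at a median absolute log2 fold change of 1.46 against 1.77. With no deeper library 5 days after breaker, its fold changes rest on the same contrast as those within the shallower set. Its signs and fold changes are therefore no further test of depth.

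Comparing the stages within the 3 lines that had both (ZL1, ZJ49 and HYL), with the line as a block, left 1522 genes, 464 higher and 1058 lower. That fit also drops ZJ7 and 7 mature green lines and adds HYL, and the same 6 libraries without the block gave 534 genes, a setting chosen after the data were seen. In the fit with the block the limma log2 fold changes were 2.96 for Capana01g003500 (adjusted p = 0.264), 6.02 for Capana06g000615 (adjusted p = 0.0565) and -2.96 for Capana00g001863 (adjusted p = 0.0701), which lost their calls, and -2.60 for Capana08g002529 (adjusted p = 0.0157). In HYL, Capana01g003500 did not rise, with 2157 RPKM at mature green and 1985 RPKM 5 days after breaker. Leaving out Zunla 1 from both arms left 2367 genes, and leaving out the library 5 days after breaker left 1362 for ZL1 and 1519 for ZJ49. Without either of these libraries Capana00g001863 lost its call, and without the ZJ49 library Capana08g002529 did, at limma adjusted p of 0.0501 to 0.0517. Scaling moved the median change from -0.24 to -0.07 and gave 2331 rises and 2533 falls, so the share of rises went from 33.9% to 47.9%.

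The 2 ripening comparisons were set side by side with Zunla 1 left out of the lines, so that they shared no library. Across the 19473 genes tested in both, Pearson's r of the log2 fold changes was 0.82 and Spearman's rho 0.71, across genes, which are not independent replicates. The lists shared 462 rises where independent lists would share 50.5, and 831 falls where 228 would be shared. Of the 4254 Zunla 1 calls among these genes, 94.3% had the same sign in the other lines, and 0 genes were called in opposite directions.

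A ripening position was computed for each fruit library from the 1070 rises and 2810 falls of the Zunla 1 series, with 0% at the mean of the 5 stages before breaker and 100% at the mean of the 3 after it. Breaker fruit of Zunla 1 lay at 55.4%. Mature green fruit of the 9 C. annuum lines lay at 11.7% ± 19.0 (SD, n = 9), from -4.12% in T803 to 56.3% in ZJ49 (without ZJ49 6.11% ± 9.66, SD, n = 8), and fruit 5 days after breaker at 93.8% ± 16.4 (SD, n = 3), from 75.1% in ZJ7 to 106% in ZL1. For the lines other than Zunla 1, which took no part in choosing the genes, the stages differed by 77.5 percentage points (2 against 8 libraries, exact two-sided permutation test, p = 0.0222, the smallest its 45 splits allow). That test treats the 10 libraries as exchangeable although ZJ49 is in both arms. With ZJ49 used only 5 days after breaker the difference was 84.1 points (2 against 7 libraries, exact two-sided permutation test, p = 0.0278), and with ZJ49 used only at mature green 64.9 points (1 against 8 libraries, exact two-sided permutation test, p = 0.111), each the smallest p possible. Within the shallower set the difference was 65.7 points (2 against 3 libraries), where the smallest possible exact p is 0.10. HYL lay at 54.1% at mature green and 101% at 5 days after breaker, and breaker fruit of chiltepin at -3.81%.

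**Figure D1:**
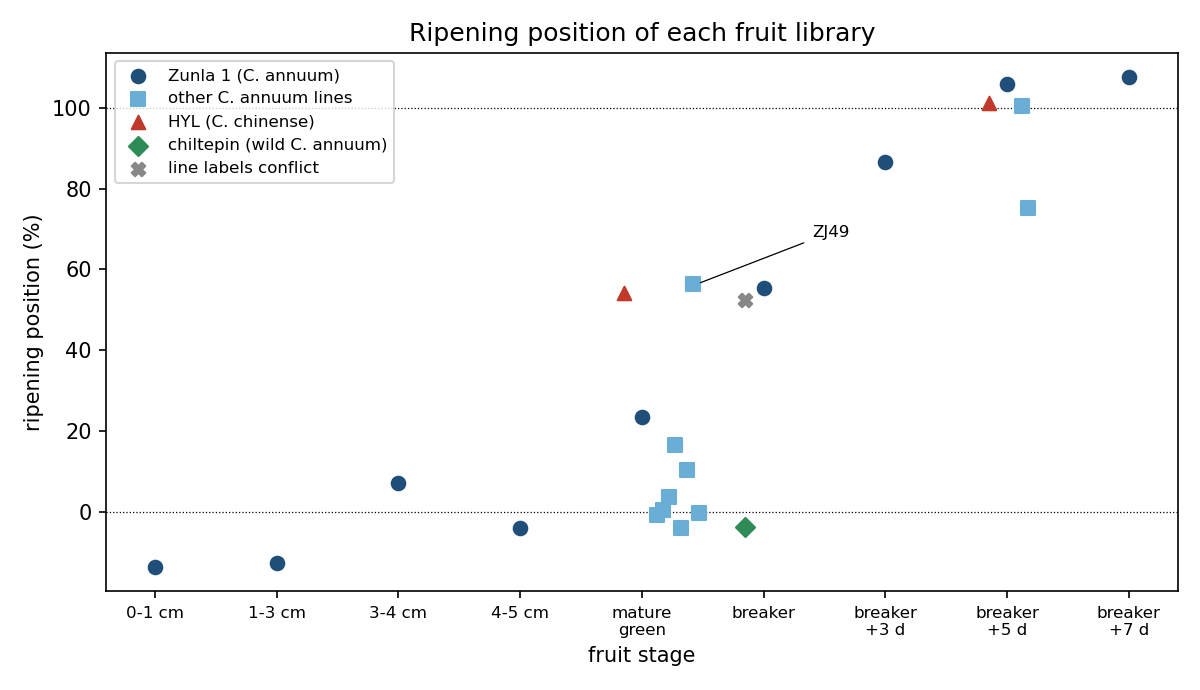
Ripening position (vertical axis, percent) of each fruit library by stage (horizontal axis), with 1 point per library and markers for the lines, spread sideways where they overlap. Zunla 1 rises from 23.3% at mature green to 107% at 7 days after breaker, ZJ49 lies at 56.3% at mature green, and chiltepin breaker fruit lies at -3.81%.

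HYL, a C. chinense line, was compared with Zunla 1 over root, stem, leaf, mature green fruit and fruit 5 days after breaker. Over the 5 pairs 1243 of 18857 genes differed, 518 higher and 725 lower in HYL, and 1234 of them at least 2-fold. Capana01g003030 was at 104 ± 24.0 RPKM (SD, n = 5) in HYL and listed at 0 in all 5 Zunla 1 libraries, and Capana00g002849 was at 164 ± 126 RPKM (SD, n = 5) against 1.01 ± 0.613 RPKM (SD, n = 5). Capana08g002048 was at 1.11 ± 0.813 RPKM (SD, n = 5) in HYL against 2201 ± 2933 RPKM (SD, n = 5), and Capana05g000522 at 0.355 ± 0.250 RPKM (SD, n = 5) against 1363 ± 2379 RPKM (SD, n = 5). In each of the 5 pairs these genes differed in the stated direction. The higher genes were not absent from C. annuum, since in mature green fruit Capana01g003030 was at 70.6 RPKM in SP3 and 43.8 RPKM in ZJ49, and Capana00g002849 was at 8777 RPKM in G16 against 331 RPKM in HYL. The lower genes were lower in HYL than in any of the 9 C. annuum lines at that stage, where the lowest values were 119 RPKM (SP3) for Capana08g002048 and 1.73 RPKM (G16) for Capana05g000522. There were 6 genes under 0.1 RPKM in all 5 Zunla 1 libraries and at 5 RPKM or more in all 5 of HYL, and 41 with the reverse pattern. Both lines were counted on the same set of gene IDs. Whether reads of HYL match these genes as well as reads of Zunla 1 was not tested. A value of 0 or a lower value in HYL therefore need not mean that a gene was less active.

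The limma log2 differences, with organ and stage as a block, were 6.04 (SE 0.427, adjusted p = 0.000301) for Capana00g002849, -8.96 (SE 0.793, adjusted p = 0.000625) for Capana08g002048 and -7.39 (SE 1.05, adjusted p = 0.00502) for Capana05g000522, and the limma adjusted p was 0.000108 for Capana01g003030. To see whether the difference reaches other lines, genes were called again from the 4 pairs other than mature green fruit, a fit chosen after the data were seen (limma, 278 higher and 618 lower). In mature green fruit of HYL, which took no part in that fit, 69.8% of the higher genes lay above all 8 C. annuum lines other than Zunla 1 and 62.6% of the lower ones below all of them, against 18.8% and 16.8% of the genes without a call. For a difference between fruit and the vegetative organs in how HYL departs from Zunla 1, no gene passed the threshold (limma, 0 of 18857 genes, lowest adjusted p = 0.0574, 2855 genes at an unadjusted p under 0.05), and 46 genes passed after scaling. Such differences were mostly out of reach, as that fit recovered 0% of 2-fold and 8.33% of 4-fold changes in simulated data, so their absence is not shown. All 10 libraries of HYL and Zunla 1 were in the shallower set, and the vegetative organs of HYL were from seedlings. Of the 8 other lines set against mature green fruit of HYL, however, 5 were in the deeper set. These 8 lines lay at a mean of 10.2% on the ripening axis, with ZJ49 at 56.3%, above HYL at 54.1%. Depth set and ripeness were thus not separated from line in the comparison with the 8 lines. Mature green fruit of HYL lay further along the ripening axis, at 54.1% against 23.3% in Zunla 1, and leaving out 1 library gave 722 without HYL leaf, 725 without Zunla 1 leaf, 749 and 760 without either stem, and 815 and 822 without either root.

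Chiltepin, the wild pepper, was compared with Zunla 1 in leaf, flower and breaker fruit. Of 20115 genes, 723 differed, 560 higher and 163 lower in chiltepin. Capana00g002849, which was also higher in HYL against the same line, was at 2045 ± 1106 RPKM (SD, n = 3) in chiltepin and at 1.29 ± 1.09 RPKM (SD, n = 4) in Zunla 1. Capana03g000778 was at 11895 ± 10043 RPKM (SD, n = 3) against 337 ± 672 RPKM (SD, n = 4). Capana05g001909 was listed at 0 in all 3 chiltepin libraries and at 100 ± 62.4 RPKM (SD, n = 4) in Zunla 1, and Capana12g001380 was at 0.0480 ± 0.0416 RPKM (SD, n = 3), under the floor, against 96.2 ± 132 RPKM (SD, n = 4). Some of these differences are not particular to the wild pepper, since Capana05g001909 was also listed at 0 in mature green fruit of the lines ZJ32 and ZJ9, and Capana03g000778 was there at 5362 RPKM in 11c255. Capana12g001380 was at 14.9 RPKM or more in mature green fruit of all 9 C. annuum lines. How well reads of chiltepin match the listed genes was not tested either, so its low values carry the same limit.

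With limma and the organ as a block, Capana00g002849 had a log2 difference of 9.76 (SE 0.568, adjusted p = 0.000969) and Capana03g000778 of 8.95 (SE 1.39, adjusted p = 0.0190), and the limma adjusted p was 0.00320 for Capana05g001909 and 0.00931 for Capana12g001380. All chiltepin libraries were in the deeper and all Zunla 1 libraries in the shallower set, so line and depth set cannot be told apart here. The count fell to 0 without the leaf of either line and to 5 without the chiltepin flower, and was 1131 without the Zunla 1 bud, 431 (311 higher) after scaling, 107 without the organ block and 35 without the filter on low values. Without either leaf all 4 genes lost their calls, at limma adjusted p of 0.103 to 0.181, and Capana03g000778 lost its call also after scaling, at 0.0576. The breaker fruit of the lines stood apart on the ripening axis, at -3.81% in chiltepin and 55.4% in Zunla 1.

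To ask which genes set each organ apart from the mean of the other 4, with line as a covariate, 16 libraries of Zunla 1, HYL and chiltepin were used. Zunla 1 fruit was taken at mature green, breaker and 5 days after breaker, and its 6 other stages were left out. Of 23889 genes, 2672 differed in root (1768 higher), 388 in stem (172 higher), 1977 in leaf (1025 higher), 3561 in flower (2016 higher) and 5141 in fruit (889 higher and 4252 lower). The gene Capana04g001405 was at 1963 ± 325 RPKM (SD, n = 2) in root and at 0.0853 ± 0.168 RPKM (SD, n = 14) in the other organs of these libraries, under the floor of the shallower libraries. In fruit outside the fit it was at 24.1 RPKM in ZJ7 and 16.4 RPKM in ZJ49 5 days after breaker. At mature green it was at 7.22 RPKM in G16, 3.02 RPKM in ZJ49 and 0.118 RPKM in SP3. It was listed at 0 there in ZJ32, ZJ9, 11c255, 11c320 and T803. Capana04g001678 was at 10518 ± 1481 RPKM (SD, n = 3) in flower and at 3.81 ± 8.33 RPKM (SD, n = 13) in the other organs. In fruit, Capana05g000916 was at 4835 ± 3298 RPKM (SD, n = 6) against 99.3 ± 207 RPKM (SD, n = 10), and Capana03g004130 was at 33.7 ± 62.1 RPKM (SD, n = 6) against 1128 ± 1361 RPKM (SD, n = 10). Stem had Capana01g001090 at 385 ± 248 RPKM (SD, n = 2) against 7.20 ± 21.1 RPKM (SD, n = 14), and leaf had Capana01g002891 at 1458 ± 555 RPKM (SD, n = 3) against 67.0 ± 109 RPKM (SD, n = 13).

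The limma log2 differences were 10.79 (SE 0.286, adjusted p = 3.84e-10) for Capana04g001405, 7.12 (SE 0.818, adjusted p = 0.00154) for Capana01g001090, 6.13 (SE 1.14, adjusted p = 0.00731) for Capana01g002891, 11.54 (SE 0.733, adjusted p = 7.46e-08) for Capana04g001678, 8.10 (SE 0.668, adjusted p = 3.21e-05) for Capana05g000916 and -6.85 (SE 0.718, adjusted p = 0.000126) for Capana03g004130. Scaling shifted the median log2 difference of all genes by -0.26 in root, -0.24 in stem, 0.34 in flower and 0.19 in fruit, and in flower 2701 genes were then higher and 824 lower, so that the share of higher calls went from 56.6% to 76.6%. The stem count rested on few libraries, with 29 genes at a pseudocount of 0.1, 859 without chiltepin, 51 without HYL stem and 19 without Zunla 1 stem, where Capana01g001090 lost its call (limma adjusted p = 0.0639). Leaving out 1 library of the organ itself gave 446 and 685 in root, 312 and 475 in leaf without the Zunla 1 or HYL leaf, where Capana01g002891 lost its call (limma adjusted p of 0.0899 and 0.0630), and 1641 and 2155 in flower without the bud or the open flower of Zunla 1. Without the libraries of the deeper set, which here are those of chiltepin, the counts were 3045 in root, 2915 in leaf, 4348 in flower and 6348 in fruit.

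**Figure D2:**
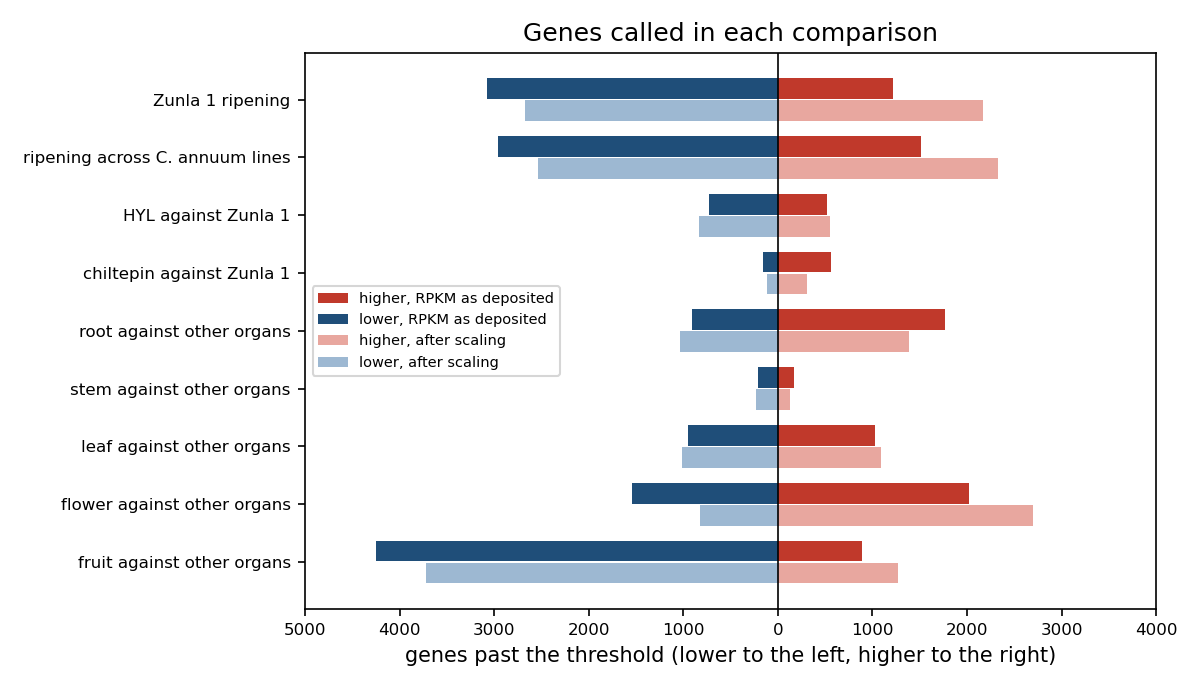
Number of genes past the threshold in each comparison with a call (vertical axis), with higher genes to the right and lower genes to the left (horizontal axis, number of genes), for RPKM as deposited (dark bars) and after median-of-ratios scaling (light bars). In fruit against other organs 4252 genes were lower and 889 higher, and in flower against other organs scaling raised the higher genes from 2016 to 2701.

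To follow organ programmes through fruit growth, gene groups were taken from the root, stem, leaf and flower libraries alone, as genes that passed in an organ and were at least 4-fold above each of the other 3. There were 653 genes for root, 24 for stem, 64 for leaf and 1242 for flower. Between the 5 earlier and the 3 later Zunla 1 stages, 0 of the 9 tested stem genes rose and 4 fell, with a median log2 change of -2.44 against -0.31 for all genes (camera in limma, adjusted p = 0.0302). With an estimated correlation the adjusted p was 0.494. The level of all 24 stem genes, including those too low in fruit to be tested, fell mostly before breaker. Its mean log2(RPKM + 1) was 2.26, 2.13, 1.48 and 1.66 in the 4 growth stages, 0.72 at mature green and 0.61, 0.66, 0.45 and 0.59 from breaker on. In the lines, 0 of 13 stem genes rose and 5 fell, with a median of -2.17 (camera in limma, adjusted p = 0.0342, and 0.886 with an estimated correlation). Adjusted over the list alone, 6 of the 9 and 7 of the 13 fell.

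The other groups did not pass the set test in Zunla 1 (camera in limma, adjusted p between 0.392 and 0.937). Of the 263 tested root genes 34 rose, 56 fell and 173 passed in neither direction, with a median log2 change of -0.76 and a mean of -0.44, and of the 490 flower genes 60 rose and 79 fell, with a median of -0.33. Among the 36 leaf genes 3 rose and 2 fell. In the lines 54 of 342 root genes rose and 36 fell, 79 of 543 flower genes rose and 62 fell, and 1 of 42 leaf genes rose and 4 fell, again without passing the set test (camera in limma, adjusted p between 0.283 and 0.837). At a pseudocount of 0.1 the balances in the lines turned, to 47 rises and 50 falls for root and 73 and 83 for flower. In Zunla 1 the balance for flower turned to 72 rises and 70 falls after scaling. The set test, which ranks a group against all other genes, pointed up for root, leaf and flower in Zunla 1 and for root and flower in the lines, although their medians and means were below 0, and after scaling it pointed down for root in both.

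**Figure D3:**
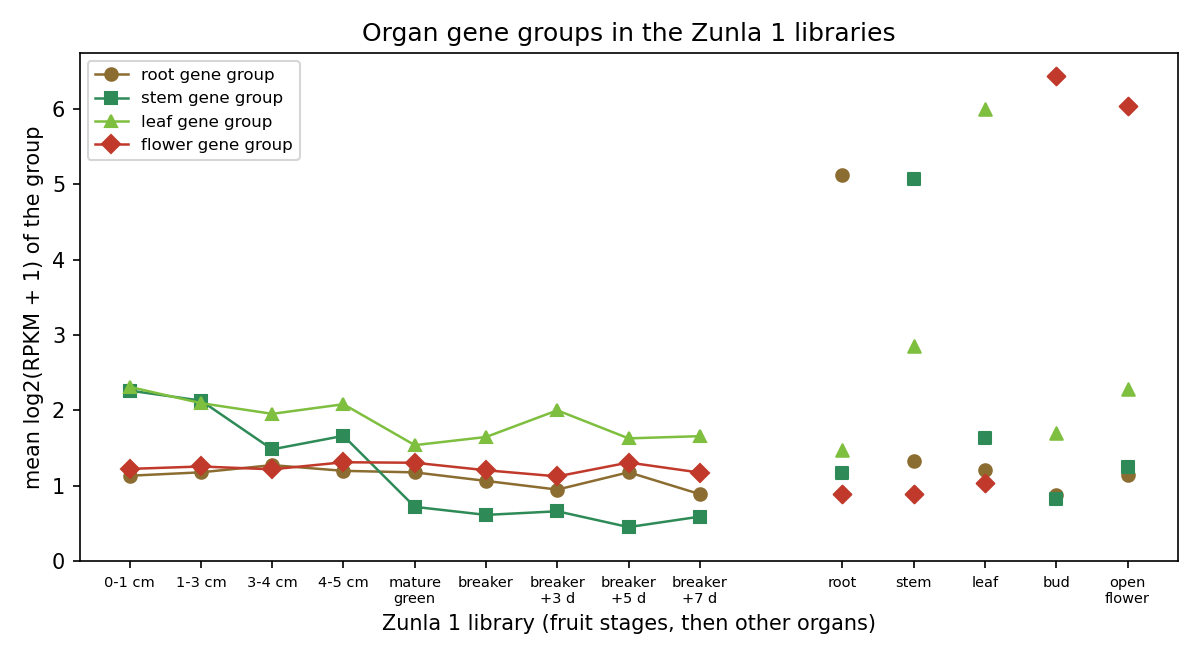
Mean log2(RPKM + 1) (vertical axis) of the root, stem, leaf and flower gene groups in each Zunla 1 library (horizontal axis), with lines joining the 9 fruit stages and single points for the other organs, from which the groups were chosen. The stem group is at 2.26 in the smallest fruit, 0.72 at mature green and 0.59 at 7 days after breaker.

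The mature green fruit of the 9 C. annuum lines was also used to count genes that were on in 1 line and off in another, with 10 RPKM or more in at least 1 line and under 0.1 RPKM in at least 1 other. There were 846 such genes. ZJ9 had 373 of them off and ZJ49 had 370, against 71 in G16 and 130 to 203 in the other 6 lines. In ZJ49 alone 162 of the genes were off, and in ZJ9 alone 142. Mature green fruit of ZJ49 lay at 56.3% on the ripening axis and that of ZJ9 at -0.271%. The ZJ49 counts may thus reflect ripeness as well as line, which was not tested. Capana01g003498 was the highest, at 4637 RPKM in ZJ49 and 2001 RPKM in ZL1 and listed at 0 in 11c255, G16, 11c320, T803 and SP3. These 5 are the deeper libraries, and all 4 shallower ones were above 0, which also held for Capana01g003500. ZJ49 and ZL1 also lay furthest along the ripening axis among the 9 lines, at 56.3% and 23.3%. Capana01g003500 is among the rises that define this axis. It was listed at 0 in the shallower Zunla 1 libraries of fruit of 0 to 1, 1 to 3 and 3 to 4 cm as well. Line, depth set and ripeness thus cannot be told apart for these genes. In all, 3 genes were off in these 5 lines and in no other, while the 125 other sets of 5 lines had a median of 0 and at most 6. Within the sets, 478 genes met the rule among the 4 shallower and 177 among the 5 deeper lines. Capana01g001197 was at 2393 RPKM in 11c255, at 22.3 RPKM in ZL1 and listed at 0 in ZJ49. These are single libraries and were not tested, 0.1 RPKM lies under the floor of the shallower libraries, and 1400 genes met the rule with 5 RPKM as the level of an active gene.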

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

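Values were looked at again where 1 mature green library of the 9 C. annuum lines stood apart from the others by a large share of the group's range (Dixon's ratio). This was asked of 13 measures, and chance marks about 1 in 20 if the values are normally distributed. For single genes the ratio was taken on RPKM without logarithms, where that rate need not hold and may be higher. The tests on the library with conflicting labels and on abundant genes in ZJ49 were chosen after the result was seen.

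Mature green fruit of ZJ49 lay at a ripening position of 56.3%, with the next line, ZL1, at 23.3%, and 2 single genes showed the same library apart, Capana01g003500 at 3525 RPKM (next highest 134 RPKM) and Capana06g000615 at 1300 RPKM (next highest 4.45 RPKM). Both genes are among the rises that define the position. A few genes that take most of the reads would show as a larger share of the 10 most abundant genes in ZJ49 than in any other line, but they held 13.5% of the summed RPKM, against 14.0% in T803, 19.7% in SP3 and 38.9% in ZL1. A swap with the other ZJ49 fruit library would place that one lower, but it lay 44.1 points higher. The depth set would place all shallower mature green libraries above the deeper ones, while 2 of the 3 others in the shallower set lay below the highest deeper one. A candidate explanation that remains, as a hypothesis, is that this fruit was further along in ripening when it was picked, and neither that nor a difference of the line itself could be tested with 1 library.

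In mature green fruit of ZL1 the 10 most abundant genes held 38.9% of the summed RPKM, more than in any of the other 8 lines.

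The breaker fruit library with conflicting labels is titled HYL and described as Zunla 1. Of 31 genes on in all 9 Zunla 1 fruit libraries and off in all 5 HYL libraries, 0% were at 1 RPKM or more in it, which argues against a Zunla 1 library titled HYL. Of 9 genes on in both HYL fruit libraries and off in Zunla 1, 100% were. These values are consistent with an HYL library described as Zunla 1, and no other C. chinense line was analysed here to set against it. Across genes it correlated best with mature green fruit of HYL (r = 0.91) but next with fruit of ZJ7, a C. annuum line, 5 days after breaker (0.88), ahead of that stage of HYL (0.86) and of breaker fruit of ZL1 (0.85), so the correlations do not separate the lines, and its ripening position was 52.4%.

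Chiltepin leaf and flower differed from those of Zunla 1, and the depth set of the libraries runs along the same line. The difference in leaf and flower correlated across genes at r = 0.31 with the difference of deeper from shallower mature green fruit of the 8 lines other than Zunla 1. The levels set beforehand were under 0.1 against the depth set and 0.5 or more for it, and the value lay between them. The 55 other splits of these 8 lines into 5 and 3 gave r from -0.34 to 0.34, with a median of -0.01, and 1 of them was as high. With that spread a value under 0.1 could not have excluded the depth set. The line and the depth set cannot be told apart. The deeper and shallower mature green libraries, all of C. annuum, differed in 2860 genes (limma), and these are also different lines. A difference between wild and cultivated pepper stays open and untested.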

How the results depend on the processing

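The settings on depth sets, chiltepin left out, the 3 lines without a block, vegetative pairs, the mature green pair and organ gene groups were chosen after seeing the data. No named gene changed direction under any setting run. Among results without a call, the set test of root genes turned from up to down in Zunla 1 (scaling, pseudocount of 0.1) and in the lines (scaling), and the median of the leaf group in Zunla 1 from -0.07 to 0.16 after scaling. The balance of rises and falls turned for flower genes in Zunla 1 (scaling) and for root and flower genes in the lines (pseudocount of 0.1). The more frequent direction of the calls turned from lower to higher in the lines within the shallower set and in stem under most left-out libraries and the pseudocount, and from higher to lower in flower and leaf under some left-out libraries and, in flower, without chiltepin. Over all settings, those printed beside the results included, 133 counts stayed within 1.5 times of the reported one, 52 moved by more and 2 went from 0 to some calls. Of the single values, 613 stayed on their side of the threshold and 63 lost their call in the same direction. The lists fixed by product name were not run, because names were lacking.

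For ripening across lines the count of 4475 was 1522 with ZL1, ZJ49 and HYL only and the line as a replicate block, 534 with these libraries and no block, 2367 without Zunla 1, 190 in the shallower depth set, 746 there with ZJ49 mature green left out and 2174 with the depth set as a term. In the depth settings the genes called in the full fit all kept their sign. Their median absolute log2 fold change was 1.48 in the shallower set, 1.60 there without ZJ49 mature green and 1.46 with the term. In the full fit it was 1.78, 1.78 and 1.77 for the same genes, so most of the change remained where calls were lost. These genes were chosen with the same libraries, and the fit with the term takes its fold changes from the same contrast as the shallower set. The cause of the falls in count was not tested. Zunla 1 ripening gave 1894 without the 2 smallest fruit stages. HYL against Zunla 1 gave 650 without the organ block, which adds the spread between organs, and the interaction of fruit against vegetative organs went from 0 to 3 at a pseudocount of 0.1 and to 46 after scaling. Chiltepin against Zunla 1 gave 35 without the filter, 431 after scaling and 107 without the organ block. Stem against other organs gave 29 at a pseudocount of 0.1 and 859 without chiltepin. With 5 RPKM as the level of an active gene, 1400 instead of 846 genes were on or off. The cause was not tested for the pseudocount, the filter or the scaling.

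Leaving out each library in turn gave 1288 to 6958 calls for Zunla 1 ripening, 1362 to 5855 for the lines, 722 to 973 for HYL, 0 to 0 for its interaction, 0 to 1131 for chiltepin, 446 to 2866 for root, 19 to 756 for stem (moved by over 1.5 times without 12 of the 16 libraries), 312 to 2555 for leaf (1278 without HYL root, 1293 without HYL stem), 1641 to 5705 for flower (5705 without chiltepin leaf), 3742 to 6123 for fruit and 639 to 822 for on or off genes. Where an arm kept 1 library, it was assumed to vary like the rest. Depth limits genes near 0.189 to 0.236 RPKM in the shallower set, and another limit is the single library per line, organ and stage. How well reads of each line match the listed genes is a further limit, and it was not tested.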

Other observations

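The real split of Zunla 1 ripening gave 4292 calls and was the only 1 of 56 splits to give as many, with 1014 as the highest other. For the lines it was the only 1 of 100 drawn, with 1750 as the highest other, a split that put mature green fruit of ZL1 in place of ZJ7, and 241 where 3 libraries of the deeper set formed the arm. Among 100 assignments of the organs to the libraries within each line, only the real 1 gave as many calls for leaf (1977, highest other 734), flower (3561, highest other 1904) and fruit (5141, highest other 1639). A chance split was thus unlikely in these 5, as far as the libraries can be exchanged. The Zunla 1 stages form a series, and ZL1 and ZJ49 stood in both arms of the lines, which the drawn splits did not keep. A structure shared by the libraries of an arm, such as neighbouring stages, was not excluded. For HYL (1243 calls, highest other 0) and chiltepin (723 calls, highest other 4) the 16 and 12 splits that keep the organ blocks, 1 of them the real split in each, are too few for a share under 0.05. Both the blocks and the draws within lines were set after splits without them had been seen.

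The chiltepin libraries were closer to each other than those of the same organs in Zunla 1. Across genes, leaf and breaker fruit correlated at r = 0.83 in chiltepin and 0.68 in Zunla 1, leaf and flower at 0.70 and 0.56, and breaker fruit and flower at 0.73 and 0.51. Flower was a flower mix in chiltepin and the open flower alone in Zunla 1. Breaker fruit of chiltepin lay at -3.81% on the ripening axis, against 55.4% in Zunla 1. It had 2.10 as the mean log2(RPKM + 1) of the stem group, against 0.61 in breaker fruit of Zunla 1. The pairs are thus not closely matched, and these are single libraries of different depth sets.

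Mature green fruit of 11c320 and 11c255 had the highest levels of the stem group among the 9 C. annuum lines, 2.75 and 2.45 as mean log2(RPKM + 1), and ZL1 the lowest, 0.72. HYL fruit 5 days after breaker had 14707 genes at 1 RPKM or more, the fewest of the 33 libraries.

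A hypothesis was that neighbouring IDs share the line pattern among genes on in some mature green lines and off in others. Of the 846 genes, 50 had another such gene within 5 ID numbers with the same set of off lines, against a median of 24 and at most 47 in 1000 permutations of the patterns. The excess is small, and it may reflect copies or segments shared by lines, or reads shared by near-identical neighbours, which were not tested.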
